A study of Macaca mulatta with 15 samples.

How the data were processed

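The series holds 15 arrays of total RNA from 5 rhesus macaque cell lines, with 3 biological replicates for each line per the labels. Per the labels' protocols, ES cells grew on mitotically inactivated mouse embryonic fibroblasts in a serum medium with FGF2, were passaged manually and were collected as colonies of undifferentiated morphology. The fibroblasts grew in another serum medium without feeders and were scraped from near-confluent dishes. RNA was extracted with TRIZOL, cleaned on columns, checked for quantity and quality, labelled with biotin and hybridised to Affymetrix rhesus arrays. Per the labels and the submitters' processing notes, the authors computed probe set signals with MAS5; its settings and version are not given in the sources used here.

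The deposited tables hold, per the file headers, a linear signal, a detection call and a detection p-value for each probe set on each array. The signal runs from 0 to 28260.8 with a median per array of 22.0 to 37.5. The authors had scaled each array, since the mean signal after trimming 2% of the values at each end was 200 on each of the 15 arrays; the values were used as deposited under the rule, set before the data were examined, that arrays within 10% of each other need no further scaling. The highest deposited detection p-value called present was 0.048995 and the lowest called absent 0.065186. The authors' deposited lists named somatic, embryonic and stemness were read for a comparison of calls only. The tables hold 195 further columns of per-sample values, which were not used. Of 52865 probe sets, 158 are controls and were left out of the tests. The 3' to 5' signal ratio of actin was 1.28 to 1.58 and that of GAPDH 1.07 to 1.41, and the 100 brightest probe sets held 7.8% to 10.0% of the signal. No arrays held identical values, and the median within-line standard deviation on the log2 scale was 0.21 in CRES-1, 0.21 in CRES-2, 0.23 in ORMES-10, 0.24 in ORMES-22 and 0.13 in the fibroblasts.

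The deposited signals were taken to log2(signal + 16), and folds are on that scale, which understates changes of dim probe sets. A probe set was tested if it was called present on all 3 arrays of at least 1 line, which left 26447. A linear model with a mean for each of the 5 lines was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend), and p-values were adjusted by the Benjamini-Hochberg method. A probe set was called at an adjusted p under 0.05 and a change of at least 2-fold. The derivation contrast is the mean of the SCNT lines minus the mean of the IVF lines, and the ES contrast the mean of the 4 ES lines minus the fibroblasts. The replicate letters entered no model, since the labels do not say that they mark a shared day. Tables were prepared and plots drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

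The 25 gene lists were fixed before the data were examined: pluripotency, fibroblast and mesenchymal, epithelial junction and keratin, neuroectoderm, mesoderm, endoderm, trophoblast, imprinted, Y-linked, X inactivation escape and XIST, DNA methylation and Polycomb, histone deacetylase and methyltransferase, DNA replication, mitosis, p53 targets, mitochondrially encoded, nuclear oxidative phosphorylation, glycolysis, cytosolic ribosomal proteins, interferon and MHC class I, heat shock and unfolded protein response, germ line, NODAL, WNT and FGF signalling, cholesterol synthesis, and housekeeping controls. They were tested with camera of limma, two-sided, with a preset correlation of 0.01 between genes, on 13554 genes with 1 probe set per gene (that of the highest mean log2 signal), and adjusted over the lists of at least 3 measured genes. Camera with an estimated correlation and fry were run beside it. For the donor profile test, genes were chosen at 4-fold or more against a single IVF line and tested against the other.

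Gene names came first from the design text of each probe set in the deposited tables and otherwise from the platform annotation, which gives a single symbol for 24969 probe sets, several for 361 and none for 27535. Older symbols were updated through the annotation (6510 probe sets) or through synonyms in a RefSeq gene table of the assembly T2T-MMU8v2.0 (430), which served for names only. In all 42673 probe sets were named with 21500 different symbols, and among 13813 that could be compared 10.6% carried another gene in the annotation. Where the design text and the annotation named different genes, the text says so beside the gene.

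The rule for named genes, set before the data were examined, took for the derivation contrast and the ES contrast the 10 called genes with the largest rise and the 10 with the largest fall. Each gene was represented by 1 probe set, that of the highest mean log2 signal, with a single symbol and no overlap between the arrays compared. Genes known by a clone name alone and probe sets whose design text and annotation disagreed were passed over there. From each list the rule added up to 4 called genes of largest change, or where none was called up to 2 members of the highest mean signal, and further each measured Y-linked gene and XIST. Comparisons of single lines took up to 5 genes each way, and POU5F1, NANOG and SOX2 were added against fibroblasts. Some genes that the rule took are not reported here; the counts over named results include them. Probe sets named by their identifiers and the genes of the axis described in the closing part were chosen after their values were seen.

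The fit was tested on simulated data for the derivation contrast with 26447 probe sets: 98 of 100 probe sets changed by 1.5 on the log2 scale and 100 of 100 changed by 3 were recovered, and 0 unchanged ones were called. Of 200 unchanged lists drawn from 13554 genes 1 had a p under 0.05, and none of 80 simulated donor profile tests did. The simulated values held no correlation between genes and no difference between lines of a derivation. They therefore do not check the calls where either is present. Alternatives set before the data were examined were quantile normalization, scaling to the median, pseudocounts of 1 and 64, no filter or a filter at the 75th percentile of mean signal, eBayes without trend, the replicate letter as a block, leaving out each array or line, no minimum change, only the arrays compared, 1 probe set per gene, and the cell line as a random block. Array quality weights and a covariate for the shared axis of replicate deviations were added after the data had been seen. No raw scans were used.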

Results

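Gene expression was measured on 15 single-colour Affymetrix arrays in 5 rhesus macaque cell lines. CRES-1 and CRES-2 are embryonic stem (ES) lines from embryos made by somatic cell nuclear transfer (SCNT), in which the nucleus of a body cell replaces that of an egg. ORMES-10 and ORMES-22 are ES lines from embryos made by in vitro fertilisation (IVF). The fifth line, 19822, is the adult skin fibroblast culture that supplied the nuclei for SCNT. Each line had 3 biological replicates per the labels, named A, B and C. Between 43.5% and 50% of the probe sets were called present on an array, that is 23015 to 26451 probe sets, and the number of arrays limits the precision. Arrays of different ES lines resembled each other far more than the fibroblast arrays: across probe sets, pairwise correlations were 0.707 to 0.753 between ES and fibroblast arrays, 0.949 to 0.983 between arrays of different ES lines and 0.966 to 0.983 within ES lines. The first principal component of the 15 arrays held 77.2% of the variance. These correlations are across probe sets, which are not independent replicates.

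Changes are given as differences of mean log2(signal + 16) with the standard error (SE) of the fit and the matching fold. Groups of genes are the 25 lists fixed before the data were examined. A list's count states how many of its measured genes passed the test of the whole array, and its adjusted p comes from a competitive list test with a preset correlation between genes.

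The main question was whether ES lines from SCNT embryos differ in expression from ES lines from IVF embryos. The clearest difference lay in genes of the Y chromosome: 6 of the 8 measured Y-linked genes rose in the SCNT lines and none fell (median change 3.91, adjusted p = 2.48e-18). DDX3Y, an RNA helicase, was higher by 6.61 ± 0.19 (97.6-fold, n = 6 and 6 arrays), USP9Y, a deubiquitinase, by 6.34 ± 0.17 (80.9-fold), RPS4Y2, a ribosomal protein, by 6.05 ± 0.20 (66.2-fold) and EIF1AY, a translation initiation factor, by 4.94 ± 0.14 (30.7-fold). KDM5D, a histone demethylase, rose by 2.88 ± 0.15 and TMSB4Y, an actin-binding thymosin, by 2.79 ± 0.18. The donor fibroblasts carried the same transcripts, with a mean log2 signal of 8.97 for USP9Y against 11.28 in CRES-1, 10.51 in CRES-2, 4.32 in ORMES-10 and 4.79 in ORMES-22. These 6 genes parted the lines as derivation did, with the donor on the SCNT side. All 6 were higher in the donor fibroblasts than in either IVF line, from EIF1AY (11.02 against 7.34 and 6.29) to KDM5D (6.06 against 4.34 in each). The fibroblasts had not passed through SCNT, so for these 6 genes the values argue against SCNT as the source of the transcripts. They go with a donor that expresses Y-linked genes. Sex and derivation still coincide among the ES lines. UTY and NLGN4Y were not called higher; their probe sets read 9.07 and 11.55 in ORMES-10, where EIF1AY read 7.34 and the other Y-linked transcripts 4.32 to 4.79, and 8.41 and 10.72 in CRES-1. The probe set read as DDX3Y is listed under another gene in the platform annotation.

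X-linked genes that escape X inactivation moved the other way, and for them the sex of the lines cannot be told apart from derivation. Of the 16 measured, 1 fell and none rose, with a median change of -0.41 (adjusted p = 1.76e-11). TXLNG, a syntaxin-binding protein of the X chromosome, fell by 1.06 ± 0.11 (2.08-fold, adjusted p = 2.44e-05), from means of 10.73 and 10.89 in the IVF lines to 9.71 and 9.80 in the SCNT lines. TXLNG reached a change of -1.0 without ORMES-22 replicate A, just short of the 2-fold limit. No probe set carried the symbol XIST.

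Imprinted genes, which are expressed from the allele of a single parent, were higher in the SCNT lines for 4 of 30 measured members and lower for none (median 0.09, adjusted p = 0.00176). NNAT, a paternally expressed proteolipid, was higher by 3.66 ± 0.10 (12.6-fold, adjusted p = 1.18e-12), NDN, a growth suppressor of neurons, by 2.47 ± 0.11 (5.54-fold), ZNF331, a zinc finger protein, by 1.33 ± 0.20 (2.51-fold) and MEST, a hydrolase-like protein of mesoderm, by 1.10 ± 0.09 (2.14-fold). The line means showed that ORMES-10 stood apart: NNAT read 12.32 in CRES-1, 11.71 in CRES-2 and 11.46 in ORMES-22 but 5.26 in ORMES-10. NDN read 8.96, 8.97 and 8.79 in those lines and 4.20 in ORMES-10, and MEST 11.46, 10.54 and 11.20 against 8.61. The platform annotation lists another gene for the NDN probe set, and ZNF331 fell short of 2-fold with a pseudocount of 64 (0.70).

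**Figure D1:**
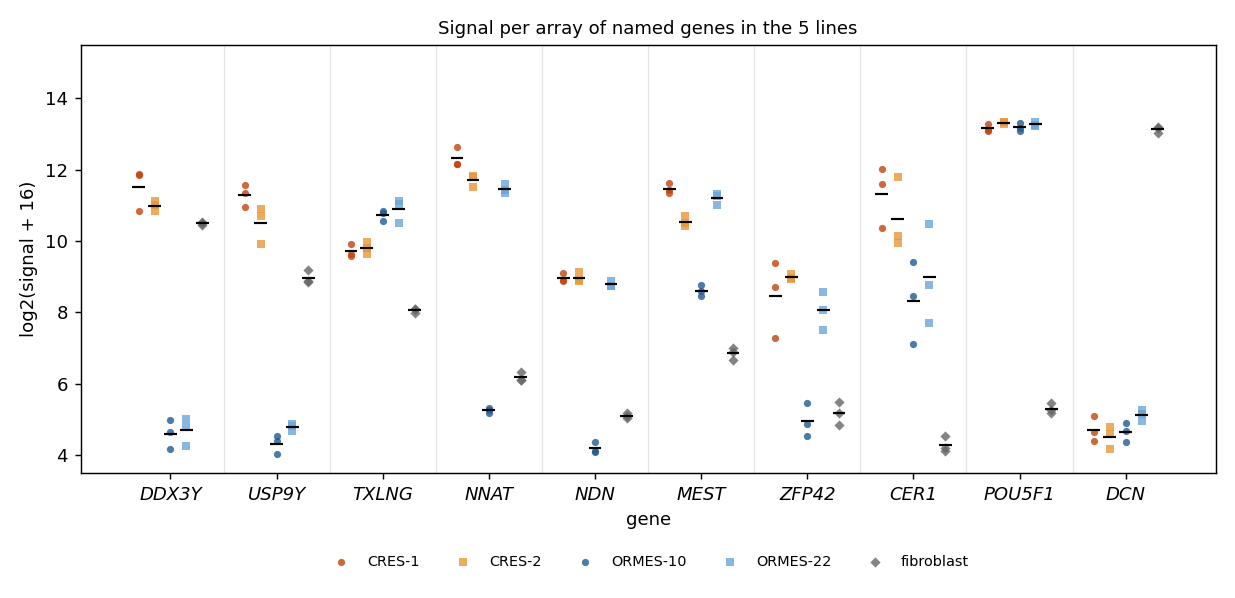
Signal per array of 10 named genes in the 5 lines, as log2(signal + 16) on the y axis; each point is an array, each black bar the mean of the 3 arrays of a line, and colours mark the lines. The Y-linked genes DDX3Y and USP9Y were near background in both IVF lines (USP9Y means 4.32 and 4.79), whereas the low values of NNAT and NDN lay in ORMES-10 alone among the ES lines (5.26 and 4.20), and POU5F1 and DCN parted all ES lines from the fibroblasts.

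Among the largest remaining rises in the SCNT lines were GSTM3, a glutathione transferase (2.49 ± 0.20, 5.62-fold), UBD, a ubiquitin-like modifier (2.19 ± 0.25, 4.56-fold), ZNF534, a zinc finger protein (2.11 ± 0.21, 4.32-fold), GZMA, a serine protease of cytotoxic lymphocytes (1.22 ± 0.15, 2.32-fold), and HLA-G, a class I antigen (1.19 ± 0.20, 2.28-fold). GSTM3 again read 8.02 in ORMES-22 and 4.96 in ORMES-10, against 8.96 and 8.99 in the SCNT lines. Under the rule for named genes, which passes over probe sets without a name and overlapping arrays, the largest falls were smaller: AARSL fell by 1.54 ± 0.23 (2.91-fold), TMT1B by 1.48 ± 0.32 (2.79-fold), the small RNA RNU71A by 1.35 ± 0.18 (2.55-fold), CAMKMT, a calmodulin methyltransferase, by 1.27 ± 0.18 (2.41-fold) and PRORP, a mitochondrial ribonuclease, by 1.21 ± 0.15 (2.31-fold). SIAH2, a ubiquitin ligase, fell by 1.18 ± 0.17 and VSTM1 by 1.12 ± 0.16. The X-linked genes HDHD1A and TBL1X fell by 1.12 ± 0.08 and 1.11 ± 0.11. Other probe sets of HDHD1A gave -0.22 and of HLA-G 0.43. A pseudocount of 64 took GZMA, HLA-G, AARSL, CAMKMT, PRORP, SIAH2 and VSTM1 below 2-fold, and TMT1B lost its call with a pseudocount of 1 (adjusted p = 0.0695).

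Genes of pluripotency did not part the derivations. Of 33 measured, 1 rose and none fell (median 0.01, adjusted p = 0.83). That gene was ZFP42, a zinc finger marker of undifferentiated cells (2.23 ± 0.29, 4.68-fold), which read 8.46 and 8.99 in the SCNT lines, 8.06 in ORMES-22 and 4.94 in ORMES-10. The 41 fibroblast and mesenchymal genes had a median of -0.04 and a test pointing down (adjusted p = 0.83; adjusted p = 0.963 with an estimated correlation). The list was called lower without CRES-1 C (adjusted p = 0.00811 with the preset correlation). A single member rose, COL1A2, a fibrillar collagen chain (1.61 ± 0.28, 3.04-fold), at 10.29 and 10.42 in the SCNT lines, 11.02 in ORMES-22, 6.48 in ORMES-10 and 14.07 in the fibroblasts.

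Lineage markers changed in few members. Of 21 endoderm genes, 2 rose (median 0.10, adjusted p = 0.00954, but adjusted p = 0.625 with an estimated correlation): CER1, a secreted NODAL antagonist (2.31 ± 0.47, 4.97-fold), and CXCR4, a chemokine receptor (1.31 ± 0.31, 2.47-fold, adjusted p = 0.0248). CXCR4 lost its call without CRES-1 B (adjusted p = 0.069), CRES-2 C (0.0677), ORMES-10 A (0.0553), ORMES-10 B (0.0546), ORMES-22 C (0.0545) or CRES-1 A (0.053), and the endoderm list without ORMES-10 B (0.0529) or CRES-2 B (0.0596). The neuroectoderm list held 1 fall among 19 genes (adjusted p = 0.992), ZIC1, a transcription factor of the dorsal neural tube (-1.27 ± 0.21), which read 8.63 in ORMES-10 and 6.10 in ORMES-22. ZIC1 fell short of 2-fold with a pseudocount of 64 (-0.96). The mesoderm list held 1 fall among 13 (adjusted p = 0.78), the cardiac factor TBX5 (-1.02 ± 0.21). TBX5 went below 2-fold without CRES-1 A (-0.93), CRES-2 A (-0.98), CRES-2 C (-0.99), ORMES-10 B (-0.87), ORMES-22 B (-0.97) or ORMES-22 C (-0.96). None of 15 trophoblast genes was called (adjusted p = 0.83), with TEAD4 at -0.30 ± 0.15.

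On the probe set taken for each gene, no gene of DNA replication, oxidative phosphorylation or cholesterol synthesis was called by limma. The list calls did not hold with an estimated correlation. The 37 DNA replication genes had a median of -0.14 (adjusted p = 0.00214; adjusted p = 0.85 with an estimated correlation), with PCNA, the sliding clamp, at -0.14 ± 0.11; without ORMES-10 B the adjusted p of the list was 0.0983. Nuclear-encoded genes of oxidative phosphorylation had a median of -0.07 over 79 genes with none called (adjusted p = 0.00388; adjusted p = 0.85 with an estimated correlation; 0.0963 without ORMES-10 A). Genes of cholesterol synthesis had a median of 0.23 over 22 genes, none called (adjusted p = 0.00638; adjusted p = 0.882 with an estimated correlation), with FDFT1, squalene synthase, at 0.31 ± 0.14. That list lost its call without ORMES-22 B (adjusted p = 0.41), CRES-2 B (0.0974), ORMES-10 C (0.0804) or CRES-1 C (0.0723). Of 2 other probe sets of FDFT1, at 0.33 and 1.16, 1 was called higher.

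Class I antigen and interferon genes changed in both directions: 2 of 26 rose and 1 fell (adjusted p = 0.15, test pointing up; 0.0251 without ORMES-10 A). MAMU-B, a macaque class I gene, rose by 1.02 ± 0.13, and went below 2-fold without ORMES-10 B (0.95), ORMES-22 C (0.89) or CRES-2 C (0.95). Of 6 mitochondrially encoded genes ATP8, a subunit of ATP synthase, fell (-1.89 ± 0.36, adjusted p = 0.00609), while the list was not called (adjusted p = 0.552). The low signal of ATP8 lay in CRES-2 alone among the SCNT lines (9.55, against 14.20 in CRES-1, 13.18 in ORMES-10 and 14.35 in ORMES-22). Of 26 heat shock and unfolded protein response genes HERPUD1 rose (1.51 ± 0.15; list adjusted p = 0.83), with other probe sets of the gene at 0.38. HERPUD1 read 8.47 in ORMES-22 and 5.55 in ORMES-10. CER1 was also the single member called among 34 genes of NODAL, WNT and FGF signalling (adjusted p = 0.391).

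No gene was called by limma in the remaining lists, and no such list was called: epithelial junction and keratin genes (27 genes, adjusted p = 0.83; CLDN6 0.10 ± 0.12), DNA methylation and Polycomb (31, 0.78; RBBP4 -0.05 ± 0.07, with several genes in the annotation), histone deacetylases and methyltransferases (30, 0.83; HDAC2 -0.01), mitosis (33, 0.83; TOP2A -0.07), p53 targets (25, 0.83; CCNG1 -0.08), glycolysis (21, 0.391; ENO1 at 0.00), cytosolic ribosomal proteins (73, 0.918; RPS3A -0.02, also with several genes), the germ line (6, 0.278; KIT 0.45 ± 0.30) and housekeeping controls (13, 0.83; ACTB -0.01 ± 0.08). Glycolysis was called higher without ORMES-10 A (adjusted p = 0.0238) and ribosomal proteins lower without CRES-1 C (0.0325). Median, mean and test differed in sign for trophoblast, ribosomal and housekeeping genes, all within 0.03 of 0.

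Across the 26447 tested probe sets, 151 rose and 60 fell in the SCNT lines at an adjusted p under 0.05 and at least 2-fold (limma; 0.798% of the probe sets, 4775 at an unadjusted p under 0.05). Of the 7 lists called with the preset correlation, 3 held with an estimated correlation: Y-linked (adjusted p = 0.00124), escape from X inactivation (0.00046) and imprinted genes (0.015). The Y-linked and X escape lists cannot tell derivation apart from the sex of the lines. The called imprinted genes read low in ORMES-10 alone among the ES lines (NNAT 5.26 against 11.46 in ORMES-22, ZNF331 4.42 against 6.86). Their calls therefore rest on that line and do not mark derivation. The rotation test fry called 4 lists; it tests whether the genes of a list move one way on balance and does not compare them with other genes. The counts adjusted over the list alone equalled those over all probe sets, except for endoderm with 4 genes. Each derivation had 2 lines, so the spread between lines of a derivation was barely sampled, and the SE and p rest on the spread of replicates within lines. A fit of 2 groups without line means, whose spread takes in that between lines, called 66 higher and 49 lower. That fit counts each array as a replicate, so the line is not its unit either.

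The spread between lines was set beside the derivation contrast by parting the same ES lines in the other possible ways. SCNT against IVF gave 211 called probe sets. CRES-1 with ORMES-10 against CRES-2 with ORMES-22 gave 85, and CRES-1 with ORMES-22 against CRES-2 with ORMES-10 gave 95. With 3 ways of pairing, no share small enough for a test can be reached. The SCNT lines came from the same donor fibroblast line, and only SCNT against IVF keeps them on the same side. The pairings are therefore not alike, and the design favoured a higher count for SCNT against IVF whether or not derivation has an effect. Without ORMES-10, 98 of the 211 probe sets were called again (46.4%), against 182 without ORMES-22, 173 without CRES-1 and 147 without CRES-2.

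The 2 SCNT lines came from the same donor fibroblast line, and they differed in mitochondrially encoded transcripts. ATP8 was higher in CRES-1 than in CRES-2 by 4.65 ± 0.51 (25.1-fold, n = 3 and 3 arrays, adjusted p = 0.000375), ND2, a subunit of respiratory complex I, by 4.36 ± 0.34 (20.5-fold, adjusted p = 8.41e-06) and ND4L, of the same complex, by 3.57 ± 0.27 (11.8-fold, adjusted p = 4.95e-06). In CRES-2 the log2 signal of ATP8 was 9.80, 7.75 and 11.11 on arrays A, B and C, while CRES-1, ORMES-22 and the fibroblasts had means of 14.20, 14.35 and 14.11. Other genes of the same genome were not called: ND5 differed by 0.06 ± 0.20, COX1 by -0.07 ± 0.12 and ND6 by 1.55 ± 0.40 (adjusted p = 0.946). ORMES-10 shared the low signals for ND2 (10.59) and ND4L (8.46) but less so for ATP8 (13.18).

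**Figure D2:**
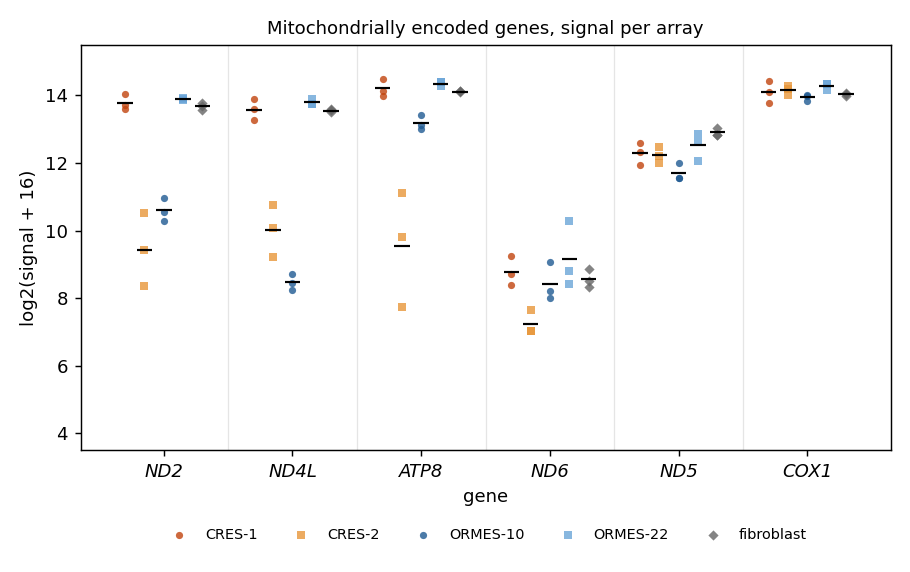
Signal per array of the 6 measured mitochondrially encoded genes, as log2(signal + 16) on the y axis; points are arrays, black bars the means of 3 arrays, and colours the 5 lines. ND2, ND4L and ATP8 were low in CRES-2 (means 9.43, 10.02 and 9.55), whereas the means of CRES-1 and CRES-2 were 12.28 and 12.22 for ND5 and 14.09 and 14.16 for COX1.

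In all, 14 probe sets were higher in CRES-1 and none lower (limma; 926 at an unadjusted p under 0.05), 4 of them with a gene name and 10 without. The list of mitochondrially encoded genes was called, with 3 of 6 genes higher, or 4 adjusted over the list alone (median 2.56, adjusted p = 3.15e-16; adjusted p = 0.00612 with an estimated correlation). Ribosomal proteins (median -0.14), p53 targets, fibroblast genes and nuclear oxidative phosphorylation genes were called lower and Y-linked and epithelial genes higher as lists, with no gene called in any of them. With an estimated correlation their adjusted p were 0.308, 0.218, 0.704, 0.704, 0.0865 and 0.646.

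The IVF lines differed from each other in more called probe sets than the derivations did (415 against 211), with fewer arrays compared. The derivation contrast averages 2 lines on each side, which shrinks a change of a single line before the 2-fold limit. Comparisons of a single SCNT with a single IVF line, the like measure, gave 363, 189, 411 and 257 calls. NNAT was lower in ORMES-10 by 73.5-fold (-6.20 ± 0.14, n = 3 and 3 arrays, adjusted p = 2.12e-13). VAPB, an endoplasmic reticulum tether, was lower by 51.0-fold (-5.67 ± 0.16), GSTO1, a glutathione transferase, by 48.5-fold (-5.60 ± 0.26), ND4L by 40.1-fold (-5.33 ± 0.27) and ZNF22, a zinc finger protein, by 30.2-fold (-4.92 ± 0.14). ZIC1 was higher in ORMES-10 by 2.53 ± 0.29 (5.78-fold), LGALS1, a galectin, by 1.79 ± 0.29 (3.45-fold) and MAMU-DPA, a class II antigen gene, by 1.69 ± 0.25 (3.23-fold). MAMU-DPA fell short of 2-fold with a pseudocount of 64 (0.87). WIRE was higher by 1.98 ± 0.31, but other probe sets of that gene gave -0.24. CAVIN2 was higher by 2.32 ± 0.52, a call that ended without ORMES-10 C (adjusted p = 0.119), ORMES-22 A (0.111) or ORMES-22 C (0.0503). Of the imprinted genes 5 of 30 were lower in ORMES-10, or 6 adjusted over the list alone (adjusted p = 0.000723; adjusted p = 0.0305 with an estimated correlation), and of the mitochondrially encoded genes 2 of 6, or 3 over the list alone (adjusted p = 4.32e-08; 0.0368 with an estimated correlation). In total 164 probe sets were higher and 251 lower in ORMES-10. A further 6 lists were called lower with the preset correlation and lost the call with an estimated one. These were fibroblast genes (adjusted p = 0.679 with an estimated correlation), epithelial genes (0.398), DNA replication (0.679), glycolysis (0.679), ribosomal proteins (0.719) and the heat shock list (0.638).

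Setting each SCNT line against each IVF line gave 363 called probe sets for CRES-1 against ORMES-10 (273 higher), 189 for CRES-1 against ORMES-22 (123 higher), 411 for CRES-2 against ORMES-10 (291 higher) and 257 for CRES-2 against ORMES-22 (164 higher). The Y-linked genes USP9Y and RPS4Y2 were among the largest rises in each: USP9Y was higher by 6.96 ± 0.23, 6.49 ± 0.23, 6.18 ± 0.23 and 5.72 ± 0.23 in that order. Against ORMES-10, NNAT led the rises, by 7.06 ± 0.14 (134-fold) in CRES-1 and 6.45 ± 0.14 (87.5-fold) in CRES-2, and VAPB was higher by 5.12 ± 0.16 and 5.44 ± 0.16. Against ORMES-22 the next largest rises were Y-linked as well, EIF1AY by 5.66 ± 0.20 and 5.27 ± 0.20. ZIC1 was lower than in ORMES-10, by -2.84 ± 0.29 and -2.24 ± 0.29. ATP8 was lower in CRES-2 than in either IVF line, by -3.63 ± 0.51 and -4.80 ± 0.51. Lists called with an estimated correlation as well were the Y-linked and X escape genes in each comparison, imprinted genes against ORMES-10 (adjusted p = 0.00243 for CRES-1 and 0.0061 for CRES-2, with an estimated correlation) and mitochondrially encoded genes for CRES-1 against ORMES-10 (0.0309) and CRES-2 against ORMES-22 (0.0132). The counts against ORMES-22 depended on single arrays. CRES-1 against ORMES-22 gave 108 calls without ORMES-22 A, 106 without CRES-1 B and 383 without ORMES-22 C; for CRES-2 they were 160 without ORMES-22 A, 149 without CRES-2 A, 167 without CRES-2 C and 473 without ORMES-22 C. Quantile normalization moved the share of higher calls from 65.1% to 50% (90 and 90) for CRES-1 against ORMES-22, and from 63.8% to 52.2% (130 and 119) for CRES-2 against ORMES-22.

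**Figure D3:**
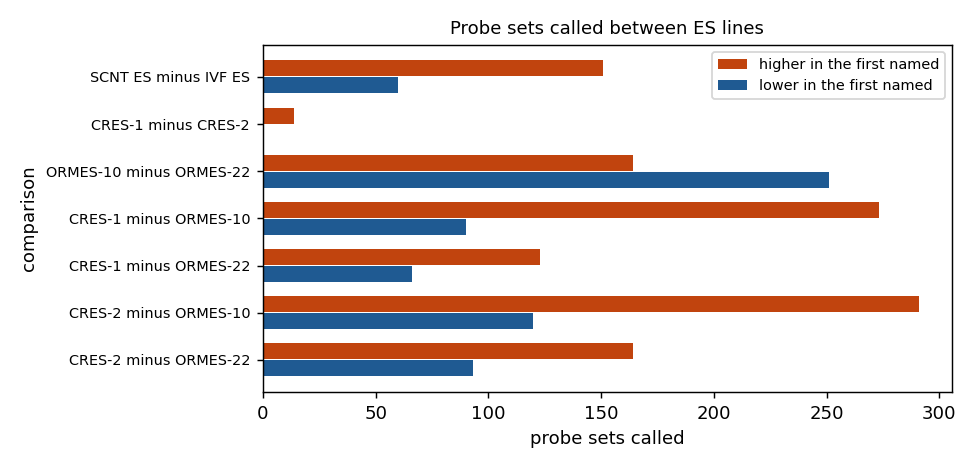
Number of probe sets called (x axis) in each comparison between ES lines (y axis), at an adjusted p under 0.05 and at least 2-fold; rust-red bars are higher and blue bars lower in the line or derivation named first. The smallest count was CRES-1 against CRES-2 (14 and 0), while ORMES-10 against ORMES-22 had 164 and 251; with quantile normalization the bars of CRES-1 against ORMES-22 become equal (90 and 90).

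The next comparison asked how far the ES lines stood from the donor fibroblasts. The lines also differed in culture medium, in the feeder layer of mouse fibroblasts under the ES cells and in harvest, since ES colonies were picked by hand and fibroblast dishes scraped whole; these cannot be told apart from cell type here. Of 33 pluripotency genes 30 rose and 2 fell in the ES lines (median 5.05, adjusted p = 1.51e-09; adjusted p = 0.108 with an estimated correlation). SOX2, POU5F1 and NANOG, the core transcription factors of the ES state, were higher by 8.06 ± 0.10 (268-fold, n = 12 and 3 arrays), 7.93 ± 0.08 (243-fold) and 6.97 ± 0.18 (126-fold). The platform annotation lists another gene for the probe sets read as NANOG and, below, TTK, OTX2 and TTR. The RNA-binding proteins LIN28B and LIN28A rose by 7.40 ± 0.14 (169-fold) and 7.19 ± 0.08 (146-fold). Of 41 fibroblast and mesenchymal genes 36 fell and 1 rose (median -2.53, adjusted p = 7.42e-13; adjusted p = 0.204 with an estimated correlation), among them the matrix proteoglycans DCN (-8.38 ± 0.17, 334-fold) and LUM (-6.55 ± 0.35, 93.5-fold), the matrix protein TGFBI (-6.93 ± 0.31, 122-fold) and the calcium-binding S100A4 (-6.52 ± 0.32, 91.9-fold). Of 27 epithelial junction and keratin genes 21 rose and 1 fell (median 3.16, adjusted p = 1.48e-06; adjusted p = 0.136 with an estimated correlation), including the claudin CLDN6 (7.23 ± 0.14, 150-fold), the adhesion molecule EPCAM (6.14 ± 0.15, 70.5-fold) and the desmosomal genes DSC2 (5.97 ± 0.09) and DSP (5.97 ± 0.14).

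Among the largest single changes were the rise of SPP1, a secreted phosphoprotein (8.55 ± 0.21, 375-fold), of KAL1, an extracellular matrix protein (8.06 ± 0.11, 268-fold), of the receptor phosphatase PTPRZ1 (6.94 ± 0.15, 123-fold) and of RBPMS2, an RNA-binding protein (6.94 ± 0.11, 123-fold). The largest falls held MMP3, a matrix metalloproteinase (-8.42 ± 0.24, 343-fold), C1QTNF3, a secreted C1q-like protein (-8.24 ± 0.24, 302-fold), SERPINB2, an inhibitor of plasminogen activators (-8.21 ± 0.19, 297-fold), FGL2, a fibrinogen-like protein (-8.15 ± 0.15, 285-fold), ALDH1A3, a retinaldehyde dehydrogenase (-7.65 ± 0.17, 201-fold), CCDC80 (-7.48 ± 0.31, 179-fold), GPNMB (-7.48 ± 0.19, 178-fold) and the cytokine IL6 (-7.45 ± 0.23, 175-fold). A probe set named ATP8B3 fell most (-9.28 ± 0.19), but other probe sets of that gene gave 0.98, so its name is in doubt.

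Many genes of cell division rose and none fell. Of 37 DNA replication genes 23 rose and none fell (median 1.42, adjusted p = 5.3e-07; adjusted p = 0.28 with an estimated correlation), with the helicase subunits MCM3 at 2.87 ± 0.11 (7.29-fold), MCM2 at 2.41 ± 0.09 (5.30-fold) and MCM7 at 2.12 ± 0.12. Of 33 mitosis genes 18 rose and none fell (median 1.18, adjusted p = 8.83e-08; adjusted p = 0.136 with an estimated correlation), with the checkpoint genes TTK (2.32 ± 0.14) and MAD2L1 (1.97 ± 0.08), the kinase AURKB (1.94 ± 0.10) and the kinesin KIF2C (1.91 ± 0.09).

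Chromatin regulators rose more often than they fell. Of 31 DNA methylation and Polycomb genes 13 rose and 2 fell (median 0.69, adjusted p = 0.0291; adjusted p = 0.136 with an estimated correlation), with the methyltransferases DNMT3B at 6.90 ± 0.13 (120-fold) and DNMT3A at 4.87 ± 0.15 (29.3-fold) and the dioxygenase TET1 at 5.38 ± 0.25 (41.6-fold). MBD2 read 5.71 ± 0.11, but its other probe sets gave -5.17, and the list was not called with the mean over the probe sets of a gene (adjusted p = 0.0955). Histone deacetylases and methyltransferases rose for 13 of 30 genes and fell for 2 (median 0.67, adjusted p = 0.0291; adjusted p = 0.502 with an estimated correlation). KDM5B, a demethylase, rose by 3.89 ± 0.21 (14.9-fold), KDM1A by 1.90 ± 0.13 and the deacetylase SIRT1 by 1.89 ± 0.13, while HDAC9 changed by -2.21 ± 0.20.

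Stress, antigen and placental genes fell more often than they rose. Of 26 interferon and class I genes 14 fell and 3 rose (median -1.04, adjusted p = 0.00249; adjusted p = 0.136 with an estimated correlation). IFI35 changed by -3.88 ± 0.22 (14.7-fold), while the membrane proteins IFITM1 (5.45 ± 0.15, 43.7-fold) and BST2 (4.51 ± 0.17, 22.8-fold) rose. Of 26 heat shock and unfolded protein response genes 9 fell and 1 rose (median -0.72, adjusted p = 0.0291; adjusted p = 0.502 with an estimated correlation; 0.12 with quantile normalization), including HERPUD1 (-3.87 ± 0.17, 14.6-fold) and the chaperone HSPA1B (-2.92 ± 0.15, 7.57-fold). Of 15 trophoblast genes 7 fell and 2 rose (median -0.79, adjusted p = 0.0291; adjusted p = 0.502 with an estimated correlation), with the growth factor receptor EGFR at -4.56 ± 0.26 (23.5-fold) and the transcription factor GATA3 at 2.71 ± 0.47 (6.56-fold). That call ended without ORMES-10 B (adjusted p = 0.0566), CRES-1 B (0.0572) or CRES-2 C (0.0585). Ribosomal protein genes were called as a list with 3 of 73 genes higher and 1 lower (median 0.23, adjusted p = 0.0291; adjusted p = 0.661 with an estimated correlation; 0.0775 without fibroblast C), a median no larger than that of all probe sets (0.26). The paralogue RPL39L rose by 1.71 ± 0.23 and RPS27L fell by 1.52 ± 0.20. With a pseudocount of 64, RPS27L fell short of 2-fold (-0.91).

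Germ layer and signalling lists changed in both directions and were not called. Neuroectoderm held 10 rises and 3 falls among 19 genes (adjusted p = 0.218), with OTX2, a homeobox factor, at 7.01 ± 0.22 (129-fold) and ZIC1 at -4.49 ± 0.23 (22.4-fold). Mesoderm held 8 and 3 among 13 (adjusted p = 0.215), with cardiac actin ACTC1 at 6.54 ± 0.12 (93.1-fold) and the receptor PDGFRA at -6.07 ± 0.24 (67.1-fold). Endoderm held 9 and 7 among 21 (adjusted p = 0.802), with CER1 at 5.52 ± 0.53 and the transport protein TTR at -5.30 ± 0.19. NODAL, WNT and FGF signalling held 18 and 7 among 34 (adjusted p = 0.316), with LEFTY2, a NODAL inhibitor, at 5.61 ± 0.84 (48.9-fold) and the receptor FGFR2 at 5.29 ± 0.19 (39.0-fold). The germ line list held 2 rises and 1 fall among 6 (adjusted p = 0.431), with the receptor KIT at 4.79 ± 0.34 (27.7-fold).

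Metabolic lists were not called either, but with all probe sets tested 4 further lists were: X escape genes (adjusted p = 0.0273), glycolysis (0.0358), nuclear oxidative phosphorylation (0.0394) and mitochondrially encoded genes (0.0394). Glycolysis held 6 rises and 1 fall among 21 genes (median 0.47, adjusted p = 0.101; 0.0393 with quantile normalization), with the kinase PDK1 at 4.09 ± 0.14 (17.0-fold) and the glucose transporter SLC2A1 at 3.64 ± 0.13 (12.5-fold). Cholesterol synthesis held 7 and 2 among 22 (adjusted p = 0.742). Nuclear oxidative phosphorylation held 4 falls and no rise among 79 (median -0.07, adjusted p = 0.101), with SDHA, of complex II, at -1.64 ± 0.09, and mitochondrially encoded genes 3 falls and no rise among 6 (median -1.01, adjusted p = 0.101), with ND4L at -2.09 ± 0.21. Imprinted genes held 11 and 8 among 30 (adjusted p = 0.959), from CDKN1C, a cell cycle inhibitor, at 4.41 ± 0.29 (21.2-fold) to TFPI2, a protease inhibitor, at -4.93 ± 0.25 (30.4-fold). Of 25 p53 targets 3 rose and 4 fell (adjusted p = 0.704), with the apoptosis gene PMAIP1 at 5.04 ± 0.22 and CDKN1A, a cell cycle inhibitor, at -3.89 ± 0.23. X escape genes held 7 rises and 1 fall among 16 (adjusted p = 0.0996). Y-linked genes held 2 and 5 among 8 (adjusted p = 0.148), and the falls average lines with and without these transcripts. The rises were NLGN4Y (6.24 ± 0.19) and UTY (1.73 ± 0.16), which did not follow the other Y-linked genes. Their probe sets read 11.55 and 9.07 in ORMES-10 but 4.85 and 6.89 in the fibroblasts. Housekeeping controls held 2 falls among 13 (adjusted p = 0.814), SDHA among them. For imprinted genes and p53 targets the median and mean were above 0 and the test pointed down, and for housekeeping controls the median was 0.14 and the mean -0.02.

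**Figure D4:**
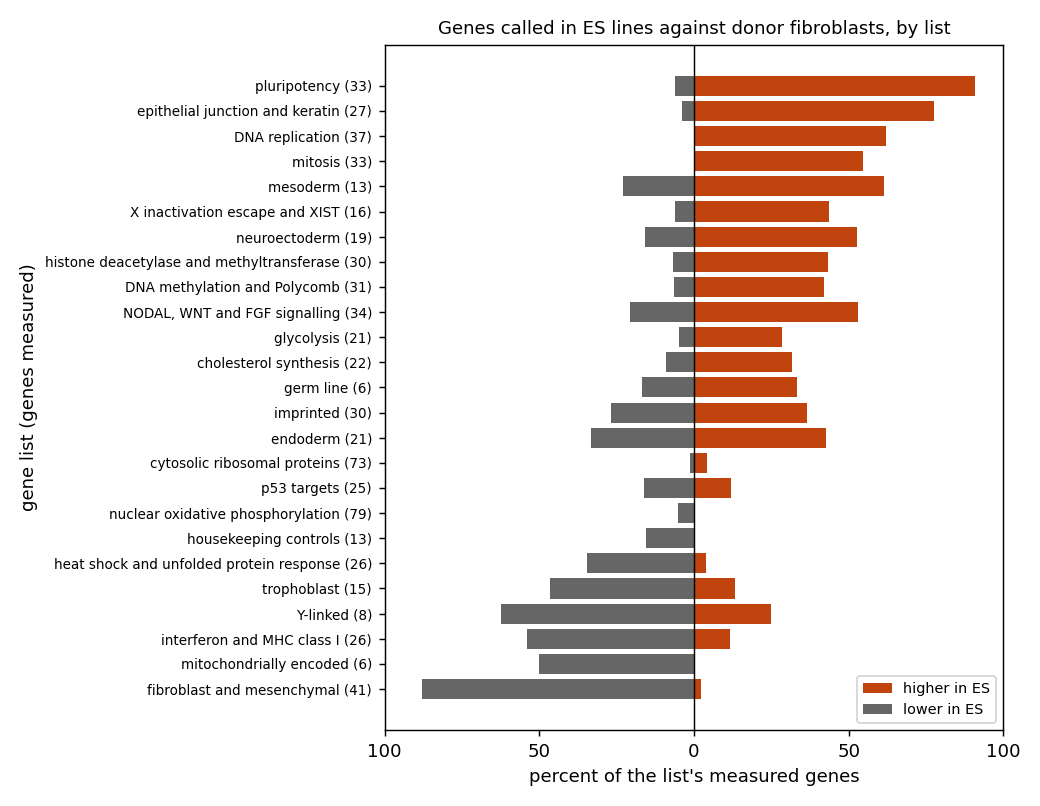
Percent of each list's measured genes called higher (bars to the right) or lower (bars to the left) in the 4 ES lines than in the fibroblasts, with the number of genes measured in parentheses. Pluripotency genes lay almost wholly to the right (30 of 33) and fibroblast genes to the left (36 of 41); with quantile normalization the balance of all calls moved from 5612 higher and 4249 lower to 4535 and 4585.

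Over all tested probe sets, 5612 rose and 4249 fell in the ES lines (limma; 37.3% of the probe sets). The median change of all probe sets was 0.26 as deposited, 0.15 with each array scaled to the same median and 0.09 with quantile normalization. Relative to that shift, the called lists other than the ribosomal proteins keep their direction. Of the 25 lists 11 were called with the preset correlation, none with an estimated correlation and 21 with fry. Counts adjusted over the list alone equalled those over all probe sets for each list.

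Each ES line on its own gave a similar count against the fibroblasts: 10232 probe sets were called for CRES-1 (6012 higher), 9900 for CRES-2 (5730 higher), 10239 for ORMES-10 (5885 higher) and 9564 for ORMES-22 (5227 higher), with 12 lists called in each and none with an estimated correlation. POU5F1 was higher by 7.86, 8.01, 7.88 and 7.96 in CRES-1, CRES-2, ORMES-10 and ORMES-22 (SE 0.10 each, n = 3 and 3 arrays). NANOG was higher by 6.96, 7.02, 7.05 and 6.86 (SE 0.22) and SOX2 by 8.01, 8.04, 7.99 and 8.21 (SE 0.13). SPP1 was higher by 8.14, 8.85, 8.45 and 8.76 (SE 0.27), and MMP3 stood at -8.23, -8.60, -8.45 and -8.41 (SE 0.30).

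Whether the SCNT lines kept part of the donor profile was tested on genes that part fibroblasts from an IVF line by at least 4-fold, in the contrast of SCNT lines with the other IVF line. The fibroblast arrays did not enter that contrast. For 1005 genes higher in fibroblasts than in ORMES-10, SCNT minus ORMES-22 lay 0.01 below other genes (median difference -0.01, adjusted p = 0.925, test pointing up), and for 1128 genes lower in fibroblasts 0.03 above (adjusted p = 0.925). For 923 genes higher in fibroblasts than in ORMES-22, SCNT minus ORMES-10 lay 0.09 above other genes, with 60.5% of the genes positive (adjusted p = 0.011; adjusted p = 0.932 with an estimated correlation). For 1075 genes lower in fibroblasts the difference was -0.01 (adjusted p = 0.925). The single call of the 4 tests was absent for CRES-1 alone (adjusted p = 0.132), with genes at least 2-fold apart (0.152) and with quantile normalization (0.148).

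The authors' deposited lists of probe sets were set beside the contrast of ES lines with fibroblasts; they were chosen on these same arrays and are not independent evidence. Of 4998 probe sets in the authors' deposited somatic list 3767 fell, 1 rose and 1230 were not called. Of 6176 in the authors' deposited embryonic list 4234 rose, none fell and 1942 were not called. All 12 probe sets of the authors' deposited stemness list rose.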

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

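The tests of donor genotype or sex, of the mitochondrial transcripts, of the replicate deviations and of the make-up of splits in this part were chosen after the results were seen; the test of other probe sets of a gene, the leaving out of lines and the counts over other splits of the arrays were not.

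A test for a single array far from the other 5 of its derivation was run on 188 sets of values of the lists and of the genes taken by the naming rule, and 8 stood apart, against 9.4 by chance alone. In CRES-1 A, ZNF534 read 6.92 (8.14 to 8.55 on the other SCNT arrays), TMT1B 4.71 (6.02 to 6.79), ZFP42 7.29 (8.71 to 9.39) and SPINT2 11.10 (10.79 to 10.88). In ORMES-10 C the mean of the housekeeping list was 11.05 (11.18 to 11.25 on the other IVF arrays) and RPS3A read 14.15 (14.38 to 14.49). UBD read 6.83 in ORMES-22 C (5.05 to 5.47) and TMT1B 8.82 in ORMES-10 B (7.05 to 7.70). Changes from the fibroblasts were compared between ES lines through the direct contrasts, in which the fibroblast mean cancels: 14 probe sets differed between CRES-1 and CRES-2, 415 between ORMES-10 and ORMES-22, and 211 between SCNT and IVF lines, the counts given above, which measure no distance from the fibroblasts.

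The probe sets that part SCNT from IVF lines could reflect the donor animal, single probe sets or a single IVF line. Leaving out ORMES-10 left 46.4% of the 211 called, so much of the list rested on that line. The fibroblast mean lay nearer to the SCNT side for 65.5% of 203 probe sets without the Y-linked genes (60.1% of 143 higher and 78.3% of 60 lower), and nearer to the first side for 66.3% (69.0% of 84 higher and 45.5% of 11 lower) and 38.8% (55.6% of 9 and 36.8% of 76) in the other pairings of the lines, so a donor genotype beyond the Y chromosome stays open. X-linked probe sets stayed in this count, so it does not set the sex of the lines aside. Sequence differences under the probes stay open as well: for 111 called probe sets with others of the same gene, the median ratio of the changes was 0.51 (bootstrap 95% interval 0.44 to 0.63 over 2000 resamples), above the range set beforehand for such differences, but with an interval that reached below the bound set to argue against them. A difference due to derivation itself stays among the open explanations, untested beyond these 4 lines.

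ATP8, ND2 and ND4L were lower in CRES-2 than in CRES-1. A lower level of all mitochondrial transcripts by a like amount is argued against by ND5, which differed by 0.06 ± 0.20. ND5 was taken for this test after its value was seen. ND6 was higher in CRES-1 by 1.55 ± 0.40 without a call, and COX1, near the top of the scale, differed by -0.07 ± 0.12. A smaller or uneven fall of the transcripts is therefore not excluded. Poorer RNA in CRES-2 is argued against by overlapping actin 3' to 5' ratios (lowest CRES-2 minus highest CRES-1 array -0.17, ranges 1.29 to 1.52 and 1.39 to 1.46). Mitochondrial sequence differences under the probes may contribute, since the changes of the 6 genes spanned 4.72 while nuclear oxidative phosphorylation genes had a median of -0.03. The signals of ATP8 (9.80, 7.75 and 11.11), ND2 (9.41, 8.36 and 10.51) and ND4L (10.07, 9.21 and 10.77) varied in the same order over CRES-2 arrays A, B and C, and this explanation cannot be told apart from a difference in transcript level, as probe sequences were not analysed here. No biological explanation beyond that common level was tested, as the labels do not give the mitochondrial genotype of the lines.

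Replicate arrays of different ES lines deviated together from their line means along an axis with 31.4% of that variance, with LEFTY1, LEFTY2, PFKFB4 and DDIT4 at its high end and MMP1, GREM1, COL8A1 and IL11 at its low end. Some first axis always exists, and its share was not set against that of unrelated arrays. RNA quality (actin ratio, r = 0.36, rho = 0.24, permutation adjusted p = 0.445 and 0.694; r = 0.01 without the 2 farthest arrays) stays undecided. More mesenchymal cells in some cultures are possible: the fibroblast list ran against POU5F1, NANOG and SOX2 (r = -0.54, p = 0.0532, adjusted p = 0.0887; rho = -0.80, p = 0.00617, adjusted p = 0.029; r = -0.54 without 2 arrays), although colonies were picked by morphology, 34 of its 41 genes were present on every ES array, 1 is in another list, and of its most abundant genes VIM (12.82 to 14.05 on ES arrays, 14.22 in fibroblasts) followed the axis at -0.78, S100A4 (6.13 to 8.48, 13.58) at -0.62, COL1A2 (6.05 to 11.79, 14.07) at -0.26 and LGALS1 (10.12 to 12.81, 13.79) at 0.01. A culture state that raises glycolysis genes is likewise open (against the fibroblast list r = -0.60, p = 0.0231, adjusted p = 0.0578; rho = -0.73, p = 0.0116, adjusted p = 0.029; r = -0.55 without 2 arrays). All were permutation tests over 5 relations of 12 arrays, exact over 1296 arrangements within lines.

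Other splits of the arrays were fitted as plain groups of arrays. For SCNT against IVF, the real count of each direction was set against the larger direction of every other split into 6 and 6. As many as the 66 higher probe sets were called in 2 of 100 splits, the real split included (95 as the highest other). For the 49 lower probe sets it was 2 of 100 as well, with the same 95 as the highest other. Most other splits mix arrays of the same line while the real one keeps lines whole, so these shares cannot exclude chance among lines. Among whole lines, 3 pairings (211, 85 and 95 probe sets) are too few for a test, and only the first keeps the SCNT lines of the shared donor together. The split with the larger count, 122 against 115 in both directions together, took arrays of each line and followed the axis above (means 0.24 and -0.24). The larger direction had a median of 0 over the other splits. The axis was drawn from these same arrays, so a split that mixes lines and has many calls tends to follow it. For gene lists 51 of 100 splits gave as many (6; highest other 11), so chance is not excluded. For ES against fibroblasts the real split alone gave as many, 1 of 100 in each direction (5591 higher and 4225 lower, with 0 as the highest other). Every other split mixed fibroblast with ES arrays, so that outcome was largely fixed by the design. With a single fibroblast line it cannot exclude chance among lines.

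The 10 splits of 3 against 3 arrays are too few for a share under 0.05. The real counts and the highest others were 9886 and 0 for CRES-1, 9547 and 0 for CRES-2, 10003 and 0 for ORMES-10 and 9198 and 0 for ORMES-22 against fibroblasts. Between ES lines they were 7 and 160 for CRES-1 against CRES-2, 240 and 0 for ORMES-10 against ORMES-22, 284 and 71 for CRES-1 against ORMES-10, 42 and 0 for CRES-1 against ORMES-22, 365 and 1 for CRES-2 against ORMES-10 and 125 and 1 for CRES-2 against ORMES-22. The split with 160 set CRES-1 A, CRES-1 B and CRES-2 C against the other SCNT arrays. It parted them along the axis above (lowest 0.07 on 1 side, highest 0.03 on the other, means 0.25 and -0.25), which was drawn from these same arrays.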

How the results depend on the processing

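Array quality weights and the axis covariate were tried only after the results were seen. Of 274 named results 46 changed call under some alternative and 8 changed sign. The 46 include genes that differed only when their other probe sets were read, where a call means that any of these was called the same way. The sign changes came with other probe sets of the gene: ATP8B3 gave 0.98 in ES lines and 1.12, 0.88, 1.11 and 0.80 in CRES-1, CRES-2, ORMES-10 and ORMES-22, MBD2 -5.17, ATP5MJ 0.16 and WIRE -0.24. The imprinted list against fibroblasts turned upward with fry (adjusted p = 1.46e-07), which does not compare it with other genes. A pseudocount of 64 ended 22 named calls, a pseudocount of 1 ended 5 and quantile normalization 3. Except where stated by construction, the cause was not tested.

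Quantile normalization, scaling to the median, no filter and eBayes without trend kept each count of called probe sets within 1.5 times. With a pseudocount of 1, 244 probe sets were higher in SCNT lines. With 64, which shrinks changes of dim probe sets, counts were 65 higher and 33 lower in SCNT lines, 3438 higher in ES lines, 189 for ORMES-10 against ORMES-22, 206 and 79 for CRES-1 and 223 and 110 for CRES-2 against ORMES-10 and ORMES-22. The filter at the 75th percentile tested fewer probe sets and gave 57 and 24 for SCNT, 2783 and 1788 for ES, 4647, 4547, 4728 and 4598 for CRES-1, CRES-2, ORMES-10 and ORMES-22 against fibroblasts, 142 between the IVF lines, 132 and 56 for CRES-1 and 153 and 87 for CRES-2 against them. Without a minimum change, a looser rule, the counts in that order were 614 and 454, 11870 and 7496, 17805, 17548, 17832 and 16970, 818, 608 and 381, and 684 and 661. With 1 probe set per gene, fewer tests, they were 80 and 23, 3047 and 2212, 5365, 5206, 5393 and 5239, 210, 200 and 66, and 222 and 79, with 3 for CRES-1 against CRES-2.

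With only the arrays compared, fewer for the spread, counts were 7 for CRES-1 against CRES-2, 240 between the IVF lines, and 42 and 125 for CRES-1 and CRES-2 against ORMES-22. Array weights gave 444 for CRES-2 against ORMES-22. A fit of 2 groups without line means, with the cell line as a random block, gave 66 higher in SCNT lines; the estimated correlation within lines was -0.01, so the block made no allowance for line, and the plain fit of 2 groups gave 66 as well. With the axis covariate 165 were higher and 62 lower. Without ORMES-10, 91 were lower; without ORMES-22, 319 were higher and 118 lower. Lists called numbered 3 with an estimated correlation and 4 with fry for SCNT against IVF, and 0 and 21 for ES against fibroblasts, where all probe sets without a filter gave 15. The donor profile call fell from 1 to 0 with an estimated correlation, genes at least 2-fold apart, CRES-1 alone and quantile normalization.

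Leaving out each replicate gave 137 to 183 higher and 58 to 69 lower in SCNT lines, 5581 to 5740 higher and 4220 to 4313 lower in ES lines, 10076 to 10499, 9767 to 10311, 10161 to 10464 and 9536 to 9804 for CRES-1, CRES-2, ORMES-10 and ORMES-22 against fibroblasts, 11 to 16 between the SCNT lines, 333 to 611 between the IVF lines, 305 to 405 and 106 to 383 for CRES-1 and 342 to 381 and 149 to 473 for CRES-2 against ORMES-10 and ORMES-22, with 5 to 8 lists for SCNT and 10 to 11 for ES.

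The replicate letters did not pair the arrays: deviations of same-letter arrays of ES lines correlated at -0.39 to 0.45, with 8 of 18 pairs over 0.1, and 6 of 15 arrays matched best with an array of their own letter. With the letter as a block 152 probe sets were higher and 60 lower in SCNT lines, the pairings gave 212, 83 and 92, 7 lists and 1 donor profile test were called, and all 274 named results kept their call. Limits: dim probe sets near the pseudocount have understated folds, saturated ones may hide differences, signal over background differs by probe set, and each derivation is known from 2 lines (without ORMES-10, 91 lower).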

Other observations

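The counts of absent probe sets and the reading of probe sets without a gene name in this part were chosen after the values were seen.

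More probe sets were called absent in ORMES-10 alone than in any other ES line alone, and sequence differences under the probes were not excluded. In this line 75 probe sets were called absent on all 3 arrays and present on the other 9 ES arrays, against 29 in ORMES-22, 2 in CRES-2 and 1 in CRES-1. Of the 75, 38 were at least 4-fold lower than in the other ES lines (median change -2.05) and 55 were present in the fibroblasts, while none of the 29 in ORMES-22 reached 4-fold (median -0.71). For 41 of the 75 the gene had other tested probe sets, whose median change was -1.78, with 29 at least 2-fold; in ORMES-22 the 18 such probe sets had a median of -0.07. Among the genes named above with low signals in ORMES-10 are the imprinted NNAT (-6.20 ± 0.14 against ORMES-22), the tether VAPB (-5.67 ± 0.16), the transferase GSTO1 (-5.60 ± 0.26) and the zinc finger gene ZNF22 (-4.92 ± 0.14).

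The largest rise and the largest fall between derivations lay in probe sets without a gene name here. Mmu.5392.1.S1_at was higher in the SCNT lines by 8.33 ± 0.15 (adjusted p = 5.01e-15, n = 6 and 6 arrays, limma), with means of 13.36 and 13.23 in CRES-1 and CRES-2, 13.09 in the fibroblasts, and 4.79 and 5.13 in ORMES-10 and ORMES-22. In the other direction MmugDNA.20222.1.S1_s_at stood at -7.36 ± 0.23 (adjusted p = 5.94e-12), with 11.82 and 11.45 in the IVF lines and 4.15, 4.41 and 4.13 in CRES-1, CRES-2 and the fibroblasts. All 6 probe sets of its design cluster were lower in the SCNT lines, from -7.36 to -3.41. MmugDNA.39107.1.S1_at stood at -5.71 ± 0.31, with 10.58 and 9.79 in the IVF lines and 4.86 in the fibroblasts. Each of these named probe sets put the fibroblasts with the SCNT lines, as the Y-linked genes above did. Sex or another trait of the donor therefore cannot be told apart from derivation for them. MmugDNA.13529.1.S1_at, also without a gene name, was higher in the SCNT lines by 2.20 ± 0.18 and did not show that pattern. It read 7.28 and 7.33 in CRES-1 and CRES-2, 5.08 and 5.13 in ORMES-10 and ORMES-22, and 6.07 in the fibroblasts, somewhat nearer to the IVF lines.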
